A study of Cricetulus griseus with 10 samples.

How the data were processed

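RNA was taken from CHO-K1 cells at passages 0, 2, 4, 6 and 10 of suspension adaptation, with 2 libraries per passage. Per the labels' protocols, total RNA was extracted with TRIzol, ribosomal RNA was removed with a Ribo-Zero kit, and stranded libraries were made with a TruSeq kit for the MiSeq sequencer. The deposited table holds 1 signal value per feature and library, made by the authors by normalising read counts with DESeq, per the submitters' processing notes, which give no version. The aligner, the counting tool, the genome build and the annotation are not given in the sources used here.

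The unit of the deposited signal was worked out from the values: in each column all values are whole multiples of the column's smallest value above 0, within 0.01 reads, as read counts divided by a size factor would be. Dividing by that step gave back whole reads. For 1 column, P4 replicate 1, the step lies so near to 1 that an automatic check of the units could not tell scaled whole reads from rounded values and advised against treating this column as counts. Its reads were still recovered in the same way, because its values are multiples of the step to within 0.0001 reads and are not whole numbers themselves, so the count-based alternatives rest on that reading for this column. The main test does not use recovered reads. The reads per library came to 12818981 and 8495567 at P0, 11157386 and 11124524 at P2, 12465671 and 10399192 at P4, 13678656 and 8394219 at P6, and 12819126 and 16599495 at P10.

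Of 25156 features, 3625 had no read in any library. There were 20050 features named by a gene number, of which 16386 were matched to a symbol through a RefSeq gene table of the CriGri-PICRH-1.0 assembly, and 5106 named by a symbol. That assembly may not be the authors' build, so no coordinates or lengths were used, only names and the chromosomes of Stab2, Acoxl and Dtnb. Features named with coordinates (30) or changed to dates by a spreadsheet (7) were not named in the text. Genes with near-identical copies, ribosomal protein genes above all, have uncertain counts because the counting rule is unknown.

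Groups and replicate numbers were taken from the labels. The main test was limma 3.58.1 (in R 4.3.3) on log2 of the deposited value plus 1, with a trended empirical Bayes prior, for the 13521 features with a mean of at least 10. All 10 libraries entered 1 fit with a mean per passage, which left 5 residual degrees of freedom and so 1 pooled spread per gene for every comparison. Contrasts were P2, P4, P6 and P10 against P0, each of the 3 later steps, and a separate slope on passage number. Tests were two-sided with Benjamini-Hochberg adjustment within a comparison at 0.05. Fold changes are differences of mean log2 values with their standard errors, and values are given as mean ± SD of normalised reads. A gene with no read in a group was set against a floor of 3 reads per library, and for 1 to 3 reads the ratio of pooled reads is given with an exact 95% binomial counting interval; floors and intervals cover counting error only.

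There were 31 gene lists with 958 entries, of which 843 matched a feature. The 28 lists with at least 5 tested members were tested with camera at a preset correlation of 0.01, adjusted over the 112 tests of 4 comparisons. With the correlation estimated per list, none of the list calls held, in any of the 4 comparisons. The 3 lists not tested were mitochondrially encoded genes (0 of 13 matched), epithelial markers (4 tested) and endothelial markers (4 tested).

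Named genes followed a fixed rule: the 12 largest rises and 12 largest falls at P10 against P0, the 6 and 6 largest at P2, P4 and P6, the 4 and 4 steepest slopes, and for steps with no call the 3 smallest p-values in each direction, among genes with a mean of at least 50 and a proper symbol. In the comparisons with P0 the 2 groups also had to be free of overlap. Only some of the step genes are given in the text. Up to 4 members with the smallest p were taken per called list, and for 6 lists at P10 whether called or not. Igfbp4 and Aqp1 were named in every passage. They were picked from prior knowledge of the study's own later work on suspension adaptation, not from a source used here. Whether that work chose them from these libraries is not known here, so their choice may not be independent of these data. Ptprc, Laptm5, Itgax at P2 and P6 and Cd68 at P6 are named outside the rule, as are the genes of the other observations. The tests, lists, rule and alternatives were fixed before the data were examined; 3 alternatives (leaving out P6 replicate 2 and P10 replicate 1 together, the log2 Dym value as a covariate, and 1 P0 library for each comparison of the overlap) and 3 contrasts (P10 against P2, P10 against P4, P6 against P2) were added after.

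The steps were tested on simulated data before use. For P10 against P0 with 13521 genes and 200 changed, limma recovered 10% of 2-fold and 77% of 4-fold changes with 6 false calls of 93, edgeR 10% and 75% with 6 of 91, and DESeq2 27% and 85% with 32 of 144. The simulation gave a gene the same spread in every passage. In the data the duplicates of P10 lay further apart than those of P0, so these rates need not hold for this comparison. Alternatives were pseudocounts of 0.1 and 5, no filter and a mean of at least 50, TMM rescaling and equal column totals, the replicate number as a block, each library left out in turn, only the libraries of the passages compared, the rank of the passage as trend variable, edgeR 4.0.16 and DESeq2 1.42.0 on recovered reads, and camera with an estimated correlation or on ranks. Where a left-out library leaves a passage with 1, that library is assumed to vary like the others. Figures were drawn with matplotlib 3.10.9.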

Results

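Gene expression was measured by RNA sequencing in CHO-K1, an established epithelial-like cell line from the ovary of the Chinese hamster, while the cells were adapted to suspension growth in a serum-free medium. There were 2 libraries at each of 5 passages of the adaptation (0, 2, 4, 6 and 10), 10 in all, abbreviated below as P0, P2, P4, P6 and P10. The reads assigned to genes per library ranged from 8394219 (P6 replicate 2) to 16599495 (P10 replicate 2). Of 25156 features, 13521 had a mean normalised read count of at least 10 and were tested. The labels do not say whether the duplicates came from separate cultures, so p-values measure only the spread between these samples, which may be technical. They also do not state how the cells of passage 0 were grown.

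The libraries of P0, P2 and P4 lay close to their duplicates, with correlations of log2 values across genes of 0.988, 0.989 and 0.992. The duplicates of P6 (0.956) and P10 (0.930) lay further apart. Since 1 spread per gene is pooled over all passages, p-values at P10 may be too small and those at P2 and P4 too large. The fits that leave out 1 library pool the spread in the same way, so passing in all of them does not remove this limit. The second principal component, with 25% of the variance, placed both P0 libraries (54.2 and 50.5) apart from the rest. The first, with 48.9%, placed P6 replicate 2 (83.3), P10 replicate 1 (67.4) and P6 replicate 1 (34.4) apart from P10 replicate 2 (-25), which lay among the P2 and P4 libraries. The feature Dym, named for a gene of Golgi organisation, held 8.53 to 13.5% of the normalised reads in the P0, P2 and P4 libraries and 10.7% in P10 replicate 2, but 4.32% and 1.15% in P6 replicates 1 and 2 and 1.41% in P10 replicate 1. Cytosolic ribosomal protein genes together held 5.65% in P10 replicate 2 and 3.68% in P10 replicate 1.

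**Figure D1:**
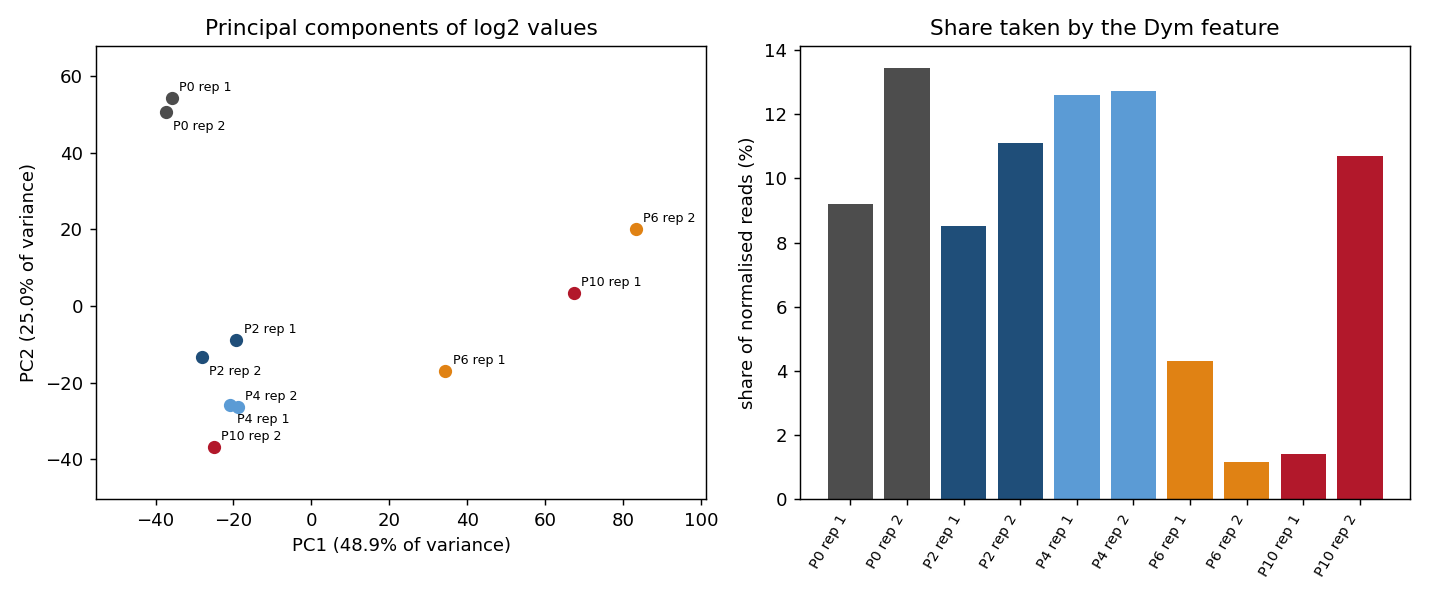
The left panel places each of the 10 libraries on the first 2 principal components of the log2 values (component scores, share of variance on each axis) and the right panel gives the percentage of normalised reads at the Dym feature per library, coloured by passage. P6 replicate 2 and P10 replicate 1 lie at 83.3 and 67.4 on the first component and have the lowest Dym shares, 1.15% and 1.41%.

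The comparison of passage 10 with passage 0 asked which genes differed between the end and the start of the sampled adaptation. Igfbp4, a secreted binding protein of insulin-like growth factors, fell from 4614 ± 1218 normalised reads at P0 to 271 ± 104 at P10 (SD, n = 2 in each passage), a ratio of 17.0. Aqp1, a water channel, fell from 699 ± 105 to 26.5 ± 25.5, a ratio of 26.4. The log2 changes were -4.11 (SE 0.33, adjusted p = 0.000304) for Igfbp4 and -5.07 (SE 0.61, adjusted p = 0.00183) for Aqp1. Both genes passed in each of the 10 fits that left out 1 library.

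Among the genes that rose at P10 was Nppa, which encodes the atrial natriuretic peptide precursor, from 5.07 ± 5.14 to 4377 ± 2237 normalised reads (log2 change 9.71, SE 0.62, adjusted p = 8.13e-05). Nppb, the precursor of a second natriuretic peptide, rose from 124 ± 2.93 to 2705 ± 1564. Agt, which encodes angiotensinogen, had no read in either P0 library and 97.1 ± 38.2 normalised reads at P10, at least 28-fold higher when 3 reads per library are taken as the floor (adjusted p = 4.84e-05). Adamtsl2, a secreted glycoprotein, had 1 read at P0 and 327 at P10, a ratio of 244 with a 95% counting interval of 43.6 to 9684. Isg15, an interferon-induced ubiquitin-like protein, had 1 and 71 reads, a ratio of 53.1 (9.22 to 2126). Col4a1, a collagen chain of basement membranes, rose from 73.1 ± 9.92 to 2827 ± 397 (log2 change 5.25, SE 0.18), and Cd36, a scavenger receptor that takes up fatty acids, from 60.3 ± 16.3 to 1748 ± 501 (log2 change 4.83, SE 0.25). Ggt1, Rxfp1 and Nrg4 rose by 4.49, 4.30 and 4.23 on the log2 scale. Stab2 and Acoxl also passed (log2 changes 5.0 and 5.64, adjusted p = 0.0394 and 0.0332), but their 2 P6 libraries differed widely, with Stab2 at 137 normalised reads in P6 replicate 1 and 6829 in P6 replicate 2.

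Nr4a3, a nuclear receptor not in the immediate early list, and 2 members of that list, Nr4a1 and Fos, had the largest falls at P10. Nr4a3 dropped from 411 ± 8.30 to 4.87 ± 0.27 normalised reads, Nr4a1 from 747 ± 62.9 to 12.8 ± 6.17, and Fos from 1106 ± 33.6 to 33.9 ± 20.5, with log2 changes of -6.13 (SE 0.47), -5.83 (SE 0.35) and -5.12 (SE 0.39). Of the 20 immediate early genes tested, 10 fell and 1 rose, and 9 did not pass (camera adjusted p = 1.95e-05, adjusted p = 0.441 with an estimated correlation); adjusted over the list alone, 12 fell and 2 rose. Thbs1, the matricellular protein thrombospondin 1, fell from 11074 ± 1488 to 787 ± 95.9 (log2 change -3.81, SE 0.19). Other large falls were in Sulf2, an extracellular heparan sulfatase (-3.88), the desmosomal Dsp (-3.28), the adhesion receptor Gpr133 (-3.01), the matrix protein Efemp1 (-2.98), the Wnt receptor Fzd7 (-2.95) and the transcription factor Zfhx3 (-2.81).

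**Figure D2:**
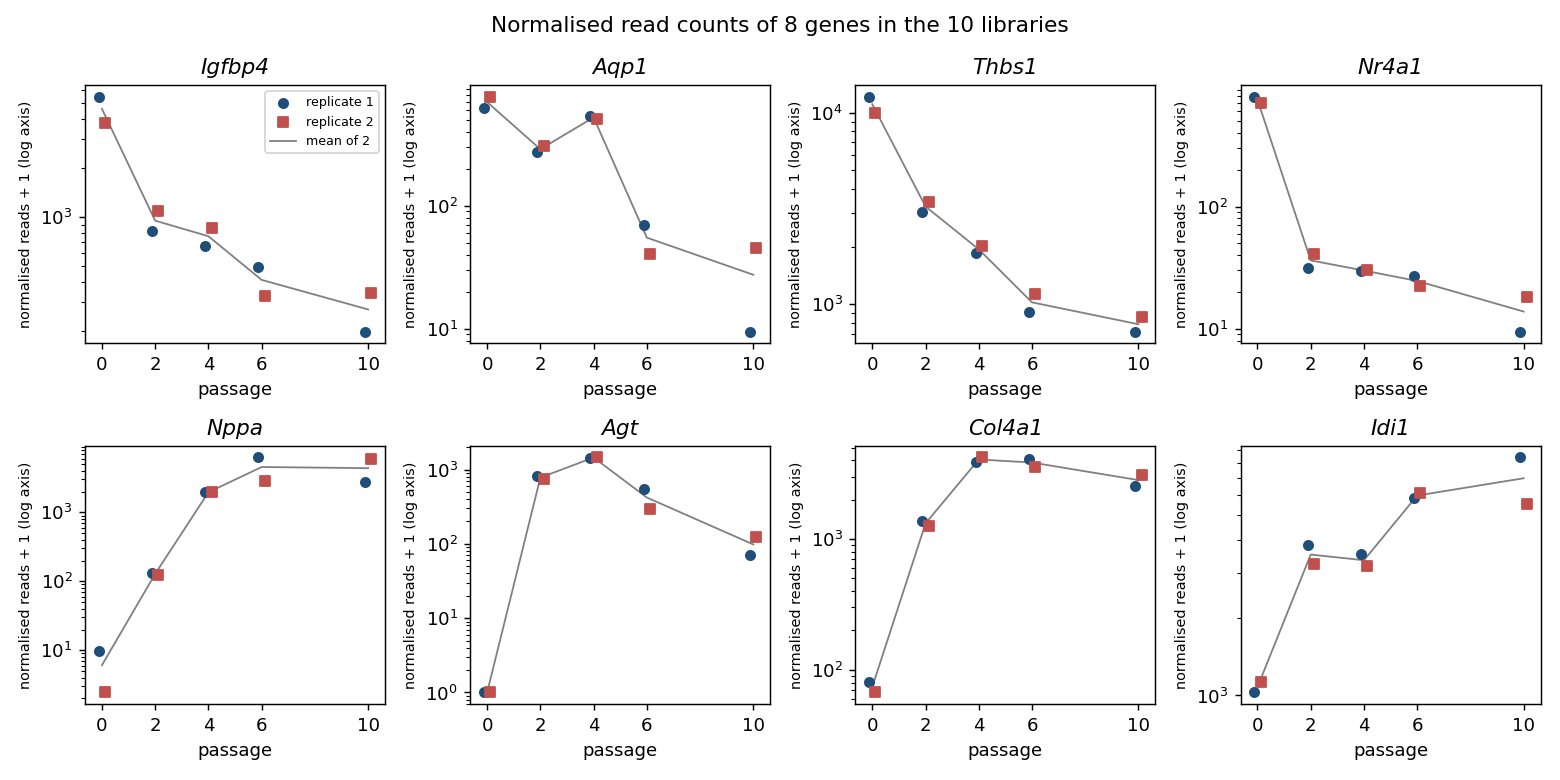
Normalised reads plus 1 on a log axis against passage for Igfbp4, Aqp1, Thbs1, Nr4a1, Nppa, Agt, Col4a1 and Idi1, with circles for replicate 1, squares for replicate 2 and a line through the mean of the 2 libraries. Igfbp4 goes from a mean of 4614 at P0 to 271 at P10, and Agt from 0 at P0 to a highest mean of 1450 at P4 and 97.1 at P10.

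Genes of cholesterol synthesis were higher at P10 as a group. Of the 21 tested, 16 rose and none fell, with a median log2 change of 1.59 (camera adjusted p = 3.68e-11, adjusted p = 0.296 with an estimated correlation), and the count was also 16 adjusted over the list alone. Idi1, an isomerase of the isoprenoid branch, rose from 1077 ± 72.2 to 6964 ± 2011 normalised reads, Msmo1, a sterol demethylase, from 1203 ± 28.4 to 4763 ± 224, and Insig1, a sterol sensor partner, from 682 ± 5.08 to 2468 ± 31.7.

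Genes of the cell cycle were also higher. In the list of DNA replication and S phase, 25 of 41 rose and none fell (median log2 change 0.96, camera adjusted p = 3.42e-12, adjusted p = 0.441 with an estimated correlation), or 32 adjusted over the list alone. Rrm2, a subunit of ribonucleotide reductase, rose from 601 ± 20.4 to 2807 ± 937, and the helicase subunit Mcm4 from 1508 ± 31.5 to 3658 ± 285. In the list of G2 and M phase, 22 of 33 rose and none fell (median 1.18, camera adjusted p = 1.12e-12, adjusted p = 0.296 with an estimated correlation), or 27 adjusted over the list alone, with Bub1b going from 433 ± 29.2 to 1189 ± 138 and Ccnb2 from 905 ± 33.6 to 3190 ± 1027.

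Of 29 genes of the NRF2 and oxidative stress list, 11 rose and 1 fell (median 0.82, camera adjusted p = 0.000401, adjusted p = 0.485 with an estimated correlation), or 15 and 1 adjusted over the list alone. Hmox1, haem oxygenase, rose by 2.46 on the log2 scale, the cystine transporter Slc7a11 by 1.96 and glutathione reductase Gsr by 1.55. Of 18 heat shock genes, 5 rose and 1 fell (camera adjusted p = 0.00317, adjusted p = 0.510 with an estimated correlation), or 8 and 1 adjusted over the list alone. Hspd1 went from 6192 ± 49.1 to 13492 ± 2652 and Hspa8 from 10720 ± 616 to 23472 ± 707, although both missed the threshold without P0 replicate 1 and without P0 replicate 2 (highest adjusted p = 0.0880 and 0.134). Of 34 nuclear genes of the respiratory chain, 5 rose and 1 fell, the same counts as adjusted over the list alone (camera adjusted p = 0.0176, adjusted p = 0.832 with an estimated correlation). Ndufa6 rose by 1.36. The list call was lost without P10 replicate 2 (adjusted p = 0.961) and without P0 replicate 1 (0.0527), and Ndufa6 without P0 replicate 1 (0.0645).

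On the lower side, 7 of 15 genes of the insulin and IGF axis fell and none rose, also adjusted over the list alone (camera adjusted p = 0.00210, adjusted p = 0.296 with an estimated correlation). Besides Igfbp4 they included the receptor Igf1r, from 2252 ± 321 to 603 ± 116, the transcription factor Foxo1, from 268 ± 78.7 to 54.2 ± 10.4, and Stc2, from 158 ± 5.83 to 8.90 ± 0.66. In the list of integrins and focal adhesion, 7 of 36 fell and 3 rose (camera adjusted p = 0.0132, adjusted p = 0.609 with an estimated correlation), or 8 and 3 adjusted over the list alone. Zyx, a focal adhesion protein, fell from 397 ± 33.3 to 68.1 ± 16.3, and the LIM protein Csrp1 rose from 2359 ± 172 to 6490 ± 1652. The integrin call was lost without P10 replicate 1 (adjusted p = 0.0726), without both P6 replicate 2 and P10 replicate 1 (0.104) and with the Dym covariate (0.0825), and Csrp1 missed the threshold without P0 replicate 1 and without P0 replicate 2 (highest adjusted p = 0.111). Of 26 target genes of YAP and SRF, 5 fell and 1 rose, also adjusted over the list alone (camera adjusted p = 0.00741, adjusted p = 0.490 with an estimated correlation). Cyr61 went from 957 ± 111 to 191 ± 42.8.

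The amino acid response and serine synthesis list had 9 genes that fell and 2 that rose of 33 (camera adjusted p = 0.0328, adjusted p = 0.734 with an estimated correlation), or 10 and 3 adjusted over the list alone. Sesn2 fell by 2.51 and Aldh18a1 by 2.48 on the log2 scale, and Slc7a11 was among the risers. This call was lost without P10 replicate 1 (adjusted p = 0.327), without both P6 replicate 2 and P10 replicate 1 (0.487), with the Dym covariate (0.472), among genes with a mean of at least 50 (0.0922) and on ranks (0.0584). Of 15 aquaporin and volume regulation genes, 4 fell and none rose (camera adjusted p = 0.0228, adjusted p = 0.441 with an estimated correlation), or 5 and 1 adjusted over the list alone. Among them were Aqp1 and Wnk1, and the call was lost without P10 replicate 1 (adjusted p = 0.0545). Extracellular matrix genes went both ways, with 5 of 32 higher and 10 lower (camera adjusted p = 0.109), or 5 and 13 adjusted over the list alone. Col4a2 rose from 4.77 ± 0.65 to 103 ± 36.8 alongside Col4a1, and Fn1, fibronectin, fell from 6477 ± 1593 to 1316 ± 40.5. Of 5 leukocyte markers, 1 rose at P10 and none fell, and the list was not called (median 0.74, camera adjusted p = 0.0750).

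**Figure D3:**
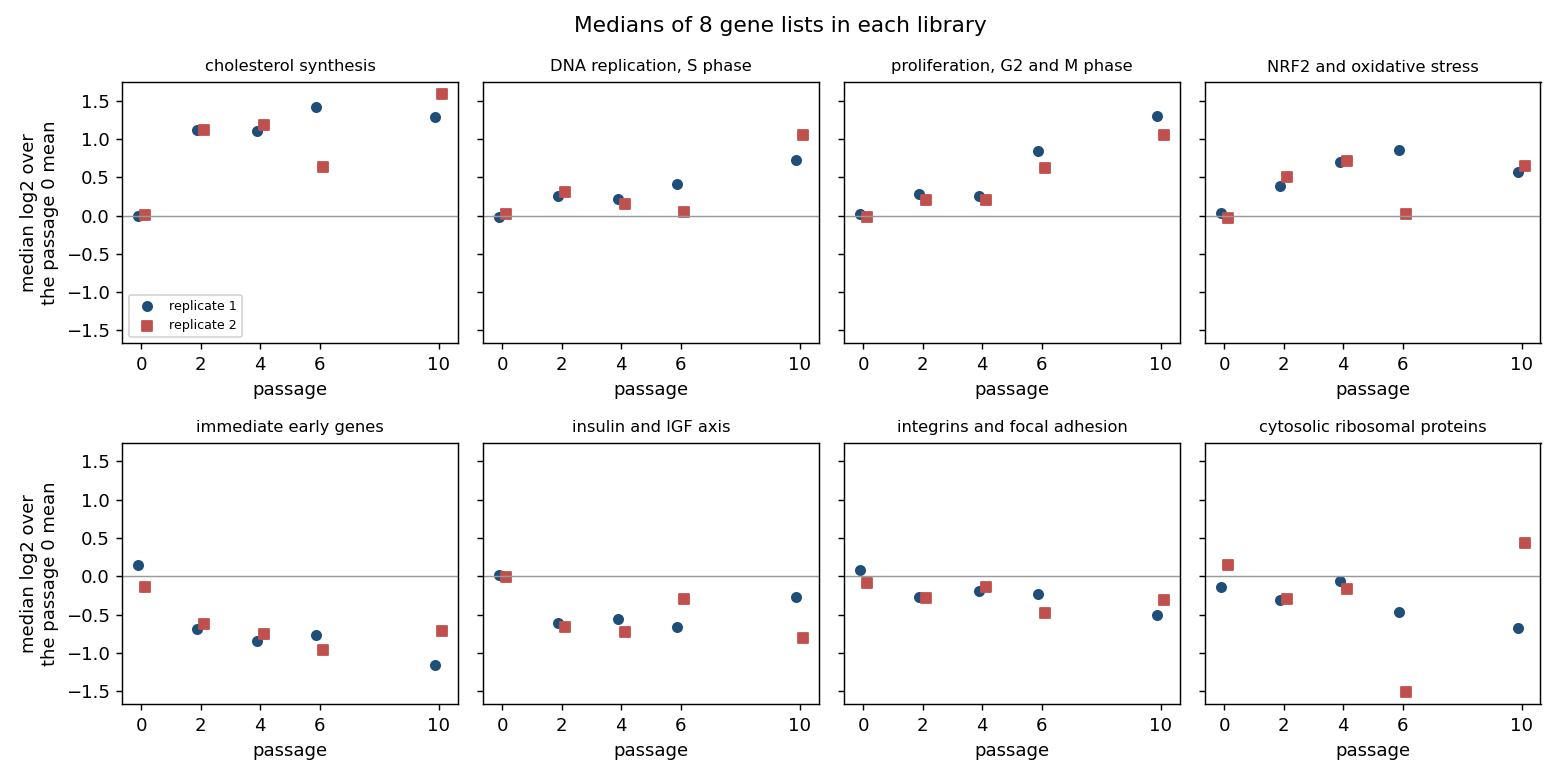
Median log2 value of the tested members of 8 gene lists in each library over the P0 mean, against passage, with circles for replicate 1 and squares for replicate 2. The cholesterol synthesis medians lie at 1.28 and 1.58 at P10, and the cytosolic ribosomal protein medians of the 2 P10 libraries lie at -0.68 and 0.43.

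In all, 1186 genes rose and 1115 fell between passages 0 and 10 by limma (2301 of 13521 at an adjusted p under 0.05). The count moved to 315 and 639 without P0 replicate 1 or 2, to 1395 and 1398 without P2 replicate 1 or 2, and to 1332 and 1334 without P4 replicate 1 or 2. It was 4738 without P10 replicate 2, 6256 without both P6 replicate 2 and P10 replicate 1, a pair chosen after the data were seen, and 49 when the spread was taken from the P0 and P10 libraries alone. Of the 67 named genes that passed, 47 passed in each of the 10 fits that left out 1 library. Fzd7 missed the threshold without P0 replicate 1 (adjusted p = 0.142), and Wnk1 without P0 replicate 1 or 2 (highest adjusted p = 0.130). Acoxl missed it without any 1 library of P0, P2 or P4 or P10 replicate 1 (0.162), and Stab2 without any 1 library of P0, P2, P4 or P10 (0.180).

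Passage 2 against passage 0 covered the first sampled change. Agt went from no read to 776 ± 58.9 normalised reads, at least 224-fold higher, and Cd36 rose from 60.3 ± 16.3 to 3452 ± 292 (log2 change 5.84, SE 0.25, adjusted p = 1.15e-05). Lum, the matrix proteoglycan lumican, rose from 2.90 ± 2.06 to 211 ± 22.2, and Isg15 had 1 read at P0 and 163 at P2, a ratio of 162 (95% counting interval 28.7 to 6438). Stab2 and Acoxl passed with log2 changes of 6.21 and 6.85. Nr4a3 and Nr4a1 fell by 4.95 and 4.38 on the log2 scale, Fos by 2.73, Ccbe1, a secreted protein of lymphatic development, by 2.66, and Gpr133 by 2.37. Igfbp4 fell to 951 ± 188 normalised reads (log2 change -2.27, SE 0.33, adjusted p = 0.00855). Aqp1, at 288 ± 22.0, did not pass (adjusted p = 0.314).

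At P2, cholesterol synthesis was the list with the highest median, 1.14, with 8 of 21 genes higher and none lower, or 16 adjusted over the list alone (camera adjusted p = 1.12e-12, adjusted p = 0.296 with an estimated correlation). Hmgcs1 rose from 1272 ± 53 to 4466 ± 45.7 and Idi1 to 3520 ± 422. Of 32 extracellular matrix genes, 8 rose and 2 fell, or 11 and 3 adjusted over the list alone (camera adjusted p = 0.000401, adjusted p = 0.441 with an estimated correlation). On ranks this call was lost (adjusted p = 0.0506). Col6a1 rose from 362 ± 81.4 to 5466 ± 1261, Col4a1 from 73.1 ± 9.92 to 1318 ± 72.2 and Postn, periostin, from 134 ± 7.42 to 683 ± 80.3, whereas Thbs1 fell to 3241 ± 281. In the interferon and inflammatory list, 5 of 21 rose and 1 fell, or 12 and 3 adjusted over the list alone (camera adjusted p = 0.000169, adjusted p = 0.453 with an estimated correlation). Irf1 and Ifi44 rose by 1.37 and 1.32 on the log2 scale, and Cxcl1, a chemokine, fell by 1.49. Of 5 leukocyte markers, 1 rose at P2, Itgax, with means of 0.719 and 36.6, and the list was not called (median 0.62, camera adjusted p = 0.0512). Of the NRF2 list, 3 of 29 rose, Hmox1, Nqo1 and Gpx1, and none fell, or 6 and none adjusted over the list alone (camera adjusted p = 0.00111, adjusted p = 0.490 with an estimated correlation).

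The calls of 3 further lists at P2 rested on small shifts of many members. The DNA replication list had 1 gene higher, Rrm2, of 41, also adjusted over the list alone (median 0.24, camera adjusted p = 0.00478, adjusted p = 0.734 with an estimated correlation). None of 33 genes of G2 and M phase passed, also adjusted over the list alone (median 0.23, camera adjusted p = 0.0259, adjusted p = 0.609 with an estimated correlation). This call was lost without P2 replicate 1 (adjusted p = 0.0632). The proliferation marker Mki67, a member of the list, had means of 3719 at P0 and 1567 at P2 (log2 difference -1.22, adjusted p = 0.179), and of 1012, 2229 and 2266 at the later passages. None of 34 respiratory chain genes passed, also adjusted over the list alone (median 0.25, camera adjusted p = 0.00867, adjusted p = 0.809 with an estimated correlation).

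Called lower at P2 were the YAP and SRF targets, with 5 of 26 lower and none higher, or 9 adjusted over the list alone (camera adjusted p = 0.000153, adjusted p = 0.441 with an estimated correlation). Among these were Cyr61 (-1.49) and Srf itself (-1.14). Of the amino acid response genes, 5 of 33 fell and none rose, or 10 and 2 adjusted over the list alone (camera adjusted p = 0.000690, adjusted p = 0.570 with an estimated correlation). Among these were Sesn2 (-1.77), Stc2 (-2.57) and the transporter Slc38a2 (-0.87). Of the insulin and IGF genes, 5 of 15 fell, or 7 adjusted over the list alone (camera adjusted p = 0.000960, adjusted p = 0.296 with an estimated correlation). Igf1r stood at 746 ± 78.7. In the immediate early list, 4 of 20 fell and 2 rose, or 10 and 2 adjusted over the list alone (camera adjusted p = 0.000726, adjusted p = 0.485 with an estimated correlation), with the feedback inhibitor Spry2 among the risers, from 252 ± 42.0 to 1016 ± 20.2. None of 68 cytosolic ribosomal protein genes passed, also adjusted over the list alone (median -0.31, camera adjusted p = 0.00911, adjusted p = 0.882 with an estimated correlation). This call was lost without P0 replicate 2 (adjusted p = 0.329); near-identical copies make counts of these genes uncertain.

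At P2, 281 genes rose and 280 fell (561 in all by limma). The count moved to 88 and 102 without P0 replicate 1 or 2, to 80 and 61 without P2 replicate 1 or 2, and to 207 and 208 without P4 replicate 1 or 2. It was 1578 and 1575 without P10 replicate 1 or 2, 4616 without both P6 replicate 2 and P10 replicate 1, 3940 from the P0 and P2 libraries alone, and 261 with the replicate number as a block. Of the 39 named genes that passed, 12 passed in each fit that left out 1 library (Agt, Cd36, Isg15, Lum, Nr4a1, Nr4a3, Spry2, Thbs1, Col4a1, Col6a1, Col6a2 and Postn). The other 27 missed the threshold without at least 1 library of P0, P2 or P4. Hmgcs1, Idi1, Cyr61, Fos and Hmox1 did so without any 1 library of P0 or P2 (highest adjusted p = 0.0859, 0.0799, 0.0949, 0.0920 and 0.124), Igfbp4 and Gpr133 without P0 replicate 1 or P2 replicate 1 or 2 (0.108 and 0.0723), Igf1r without P0 replicate 2 or P2 replicate 1 or 2 (0.0882), and Ccbe1 without replicate 2 of P0 or P2 (0.0541). Stab2, Acoxl, Rrm2, Srf, Sesn2, Stc2, Slc38a2, Nqo1, Gpx1, Irf1, Ifi44 and Cxcl1 missed it without any 1 library of P0, P2 or P4 (from 0.166 for Cxcl1 to 0.308 for Ifi44).

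At passage 4, Agt had its highest mean, 1450 ± 3.26 normalised reads, at least 419-fold above passage 0 (adjusted p = 2.45e-06). Nppa had risen to 1955 ± 6.33 (log2 change 8.65, SE 0.62), Cd36 to 3534 ± 370 (5.87, SE 0.25) and Col4a1 to 4067 ± 208 (5.78, SE 0.18). Adamtsl2 had 223 reads against 1 at P0, a ratio of 220 (95% counting interval 39.1 to 8730). Stab2 and Acoxl passed with log2 changes of 6.56 and 7.13. Nr4a3, Nr4a1 and Fos fell by 5.22, 4.64 and 3.31 on the log2 scale, Gpr133 by 3.29, Sulf2 by 2.84 and the early response factor Egr1 by 2.82. Igfbp4 was lower, at 763 ± 136 (log2 change -2.58, SE 0.33, adjusted p = 0.00321). Aqp1, at 524 ± 17.4, did not pass (adjusted p = 0.749).

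Of the lists called higher at P4, cholesterol synthesis had the smallest camera p, with 11 of 21 genes higher and none lower, or 16 adjusted over the list alone (median 1.11, camera adjusted p = 8.36e-11, adjusted p = 0.296 with an estimated correlation), Insig1 at 1768 ± 110 among them. Of the NRF2 list, 9 of 29 rose and none fell, or 11 adjusted over the list alone (median 0.71, camera adjusted p = 0.000105, adjusted p = 0.456 with an estimated correlation). Hmox1 stood at 2497 ± 372. Of the extracellular matrix list, 9 of 32 rose and 3 fell, or 10 and 4 adjusted over the list alone (camera adjusted p = 0.00462, adjusted p = 0.485 with an estimated correlation). Col4a2 and Col6a1 rose by 4.39 and 3.72, and Thbs1 fell by 2.51. On ranks the matrix call was lost (adjusted p = 0.0649). The interferon and inflammatory list had 7 of 21 higher and 2 lower, or 11 and 3 adjusted over the list alone (camera adjusted p = 0.000923, adjusted p = 0.485 with an estimated correlation). The complement gene C3 stood at 75 ± 10.9 against 15.2 ± 3.17. Of the lysosome and autophagy list, 4 of 39 rose and 1 fell, or 4 and 2 adjusted over the list alone (camera adjusted p = 0.00466, adjusted p = 0.661 with an estimated correlation). The protease Ctsa stood at 16737 ± 782 against 4415 ± 295. Respiratory chain genes rose in 4 of 34 cases with none lower, also adjusted over the list alone (camera adjusted p = 0.000946, adjusted p = 0.734 with an estimated correlation). Ndufa4 was higher by 0.95.

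Of the TGF-beta and mesenchymal list, 6 of 27 rose and none fell, or 7 adjusted over the list alone (camera adjusted p = 0.0354, adjusted p = 0.441 with an estimated correlation). Timp1 stood at 3159 ± 254 against 1103 ± 3.56 and Mmp12 at 973 ± 23.8 against 146 ± 17.5. That call was lost without P0 replicate 2 (adjusted p = 0.123), P4 replicate 2 (0.0576), P10 replicate 1 (0.0770), P10 replicate 2 (0.0780) or both P6 replicate 2 and P10 replicate 1 (0.152). It was also lost with the Dym covariate (0.0825), among genes with a mean of at least 50 (0.0779) and on ranks (0.118). Of the DNA replication list, 2 of 41 rose, Rrm2 and Gins1, or 1 adjusted over the list alone (camera adjusted p = 0.0491, adjusted p = 0.832 with an estimated correlation), and the call was lost without P0 replicate 1 (adjusted p = 0.0844), P2 replicate 1 (0.0559), P2 replicate 2 (0.0548) or P4 replicate 1 (0.109). It was also lost with the replicate block (0.0536), TMM rescaling (0.0529) and equal column totals (0.0523). Among markers of leukocytes, a cell type not part of the culture, Itgax and Cd68 rose of 5 tested, also adjusted over the list alone (camera adjusted p = 0.0259, adjusted p = 0.441 with an estimated correlation); Itgax had 1 read at P0 and 139 at P4, a ratio of 137 (95% counting interval 24.2 to 5456), while the general leukocyte marker Ptprc had means of 14.1 and 12.3. The leukocyte call was lost on ranks (adjusted p = 0.0948) and without both P6 replicate 2 and P10 replicate 1 (0.0911). Called lower were the immediate early list, with 8 of 20 lower and 1 higher, or 12 and 2 adjusted over the list alone (camera adjusted p = 0.000251, adjusted p = 0.485 with an estimated correlation), and the insulin and IGF list, with 5 of 15 lower and none higher, or 7 and 1 adjusted over the list alone (camera adjusted p = 0.00550, adjusted p = 0.311 with an estimated correlation). Irs1 fell by 1.22. The insulin and IGF call was lost on ranks (adjusted p = 0.0506).

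At P4, 503 genes rose and 747 fell (1250 in all by limma). The count moved to 177 and 338 without P0 replicate 1 or 2, to 698 and 697 without P2 replicate 1 or 2, and to 152 and 143 without P4 replicate 1 or 2. It was 2783 and 2762 without P10 replicate 1 or 2, 5829 without both P6 replicate 2 and P10 replicate 1, 5677 from the P0 and P4 libraries alone, and 767 with the replicate block. Of the 50 named genes that passed, 25 passed in each fit that left out 1 library. Of those named at P4, Irs1, Ndufa4, Stab2 and Acoxl missed the threshold without any 1 library of P0 or P4 (highest adjusted p = 0.122, 0.103, 0.162 and 0.157), Cd68 and Gins1 without any 1 library of P0, P2 or P4 (0.234 and 0.311), Egr1 and Rrm2 without P0 replicate 1 or P4 replicate 1 or 2 (0.110 and 0.0606), and C3 without P4 replicate 2 (0.0595).

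At passage 6, Nppa stood at 4551 ± 2424 normalised reads (log2 change from passage 0 of 9.76, SE 0.62, adjusted p = 9.14e-05), Agt at 419 ± 184, at least 121-fold above P0, and Rxfp1, the relaxin receptor, at 656 ± 129 against 10.1 ± 1.97. Cd36 and Col4a1 were higher by 5.86 (SE 0.25) and 5.70 (SE 0.18) on the log2 scale, and Adamtsl2 had 399 reads against 1, a ratio of 339 (95% counting interval 60.6 to 13436). Igfbp4 fell to 412 ± 120 (log2 change -3.49, SE 0.33, adjusted p = 0.000718) and Aqp1 to 54.1 ± 20.9 (-3.71, SE 0.61, adjusted p = 0.00561). Nr4a1 and Nr4a3 fell by 4.93 and 4.68. The features Lck, Tex14, Il17b and Was were also among the largest falls, at -5.37, -4.41, -4.14 and -3.72; Tex14 and Was had 165741 ± 64905 and 6102 ± 4990 normalised reads at P0, and the duplicates of P0 and P6 lay far apart in these features. So did those of P10: Tex14 had 17923 and 116089 in P10 replicates 1 and 2, Il17b 166 and 4373, Lck 46.4 and 493, and Was 698 and 2639, low in the libraries in which Dym was low.

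Both cell cycle lists were called higher at P6. Of 33 genes of G2 and M phase, 19 rose and 1 fell, also adjusted over the list alone (median 0.72, camera adjusted p = 1.14e-06, adjusted p = 0.441 with an estimated correlation). Ccnb2 stood at 2641 ± 155 and Nusap1 at 2542 ± 125. Of the DNA replication list, 8 of 41 rose and none fell, also adjusted over the list alone (median 0.25, camera adjusted p = 0.0160, adjusted p = 0.749 with an estimated correlation). This call was lost without P6 replicate 1 (adjusted p = 0.346). Cholesterol synthesis had 11 of 21 genes higher and none lower, or 13 adjusted over the list alone (camera adjusted p = 6.36e-07, adjusted p = 0.441 with an estimated correlation). Sc5d, the desaturase of sterols, stood at 4000 ± 485 against 1204 ± 19.6. The NRF2 list had 10 of 29 higher and 1 lower, or 11 and 1 adjusted over the list alone (camera adjusted p = 0.0218, adjusted p = 0.661 with an estimated correlation), and the interferon list 5 of 21 higher and 2 lower, also adjusted over the list alone (camera adjusted p = 0.0328, adjusted p = 0.663 with an estimated correlation). Without P6 replicate 1 these calls were lost (adjusted p = 0.147 for NRF2 and 0.194 for interferon). The interferon call was also lost among genes with a mean of at least 50 (0.0864) and on ranks (0.0502). Of the 5 leukocyte markers, 2 rose at P6 (Itgax and Cd68) with a median of 1.53, but the list was not called (camera adjusted p = 0.0584). Laptm5 had means of 2.61 at P0 and 26.2 at P6, and Ptprc of 14.1 and 23.6, and neither passed.

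Cytosolic ribosomal protein genes were lower at P6, with 15 of 68 lower and none higher, or 22 and 1 adjusted over the list alone (median -0.99, camera adjusted p = 7.65e-06, adjusted p = 0.748 with an estimated correlation). Rpl19 went from 15098 ± 1304 to 5327 ± 2477, and the list medians of P6 replicates 1 and 2 were -0.47 and -1.52; Rpl19 missed the threshold without P0 replicate 1 or 2 or P6 replicate 2 (highest adjusted p = 0.126). With the Dym covariate the ribosomal call was lost (adjusted p = 0.758). Of the immediate early list, 10 of 20 fell and 2 rose, or 11 and 2 adjusted over the list alone (camera adjusted p = 0.00210, adjusted p = 0.492 with an estimated correlation). Of 15 aquaporin and volume regulation genes, 6 fell and 1 rose, or 8 and 1 adjusted over the list alone (camera adjusted p = 0.0259, adjusted p = 0.441 with an estimated correlation). Sgk1, a salt-responsive kinase, stood at 1434 ± 329 against 3207 ± 42.9. Of the integrin list, 8 of 36 fell and 1 rose, or 9 and 3 adjusted over the list alone (camera adjusted p = 0.0457, adjusted p = 0.700 with an estimated correlation). Zyx fell by 2.81. Of the amino acid response list, 9 of 33 fell and 3 rose, or 10 and 3 adjusted over the list alone (camera adjusted p = 0.0491, adjusted p = 0.749 with an estimated correlation). Stc2 fell by 3.63. Of the insulin and IGF list, 6 of 15 fell and 1 rose, or 7 and 1 adjusted over the list alone (camera adjusted p = 0.0491, adjusted p = 0.441 with an estimated correlation). The integrin call was lost without P0 replicate 1 (adjusted p = 0.118), P6 replicate 1 (0.0750), P6 replicate 2 (0.0647), P10 replicate 1 (0.0599), P10 replicate 2 (0.0589) or both P6 replicate 2 and P10 replicate 1 (0.104). It was also lost with the Dym covariate (0.237), among genes with a mean of at least 50 (0.0621), with equal column totals (0.0544) and on ranks (0.0544). The amino acid call was lost without P0 replicate 1 (0.0722), P6 replicate 2 (0.263) or both P6 replicate 2 and P10 replicate 1 (0.273). It was also lost with the Dym covariate (0.970), among genes with a mean of at least 50 (0.155), with TMM rescaling (0.0521) and on ranks (0.0577). The insulin and IGF call was lost without P6 replicate 1 (0.136), P10 replicate 1 (0.104) or P10 replicate 2 (0.104), with the replicate block (0.0536) and on ranks (0.129).

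At P6, 1418 genes rose and 1423 fell (2841 in all by limma). The count moved to 412 and 702 without P0 replicate 1 or 2, to 1629 without P2 replicate 1 or 2, to 1567 without P4 replicate 1 or 2, and to 1800 and 1651 without P6 replicate 1 or 2. It was 5439 and 5441 without P10 replicate 1 or 2, and 6595 without both P6 replicate 2 and P10 replicate 1. Of the 53 named genes that passed, 29 passed in each fit that left out 1 library. Aqp1 missed the threshold without P0 replicate 1 (adjusted p = 0.0506), Sgk1 likewise (0.0539), Lck without P0 replicate 2 (0.0643), Was without replicate 2 of P0 or P6 (0.0675), Tex14 without P0 replicate 1 or 2 or P6 replicate 2 (0.0731), and Il17b without any 1 library of P0, P2, P4 or P6 (0.201).

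The 3 steps between successive sampled passages after P2 gave no gene at an adjusted p under 0.05 by limma. From P2 to P4, 285 genes had an unadjusted p under 0.05, with 0 calls by edgeR and 10 by DESeq2. Col4a1 had means of 1318 ± 72.2 and 4067 ± 208 (adjusted p = 0.102) and Postn of 683 ± 80.3 and 188 ± 2.10 (adjusted p = 0.102). From P4 to P6, 3450 genes had an unadjusted p under 0.05, with 0 calls by edgeR and 463 by DESeq2. Fabp4, a fatty acid carrier, had means of 996 ± 28.8 and 291 ± 74.5 (adjusted p = 0.138), Pfn1, profilin, of 669 ± 3.83 and 1898 ± 200 (adjusted p = 0.161), and Aqp1 of 524 ± 17.4 and 54.1 ± 20.9 (adjusted p = 0.179). From P6 to P10, 1273 genes had an unadjusted p under 0.05, with 0 calls by edgeR and 67 by DESeq2. Cdc6, a replication licensing factor, had means of 201 ± 44.9 and 411 ± 41.5 (adjusted p = 0.457) and Efemp1 of 1272 ± 18.1 and 532 ± 99.3 (adjusted p = 0.318). The counts moved with the P6 and P10 libraries that entered the fit. All comparisons share 1 pooled spread per gene, which takes in the wide differences between the duplicates of P6 and P10. Without P10 replicate 1 or 2, P4 to P6 gave 3673 and 3676 calls, and without P10 replicate 1, P6 to P10 gave 2936. P2 to P4 gave 9 and 4 without P10 replicate 1 or 2 and 2 without P2 replicate 1, and without P6 replicate 2 the other steps gave 9 and 6. Without both P6 replicate 2 and P10 replicate 1 the steps gave 220, 3712 and 3610 calls.

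A slope per passage over all 10 libraries asked which genes had a linear trend, and 828 had a rising and 595 a falling slope (1423 in all by limma). A slope does not show a steady course: Nr4a3 had means of 411, 12.4, 10.1, 17.2 and 4.87 over the 5 passages, and Aqp1 of 699, 288, 524, 54.1 and 26.5. Nppa had a slope of 0.93 on the log2 scale per passage (SE 0.17, adjusted p = 0.0123), Ggt1 of 0.44 (SE 0.08, adjusted p = 0.00981) and Nrg4 of 0.39 (SE 0.08, adjusted p = 0.0154). Aqp1 had -0.53 (SE 0.08, adjusted p = 0.00762), Fos -0.45 (SE 0.06, adjusted p = 0.00584), Nr4a1 -0.48 (SE 0.11, adjusted p = 0.0220) and Nr4a3 -0.47 (SE 0.13, adjusted p = 0.0389). Ggt1 and Fos passed in each fit that left out 1 library. Aqp1 missed the threshold without P10 replicate 1 (adjusted p = 0.0535), Nppa without P0 replicate 1 (0.0564), Nr4a1 and Nrg4 without P0 replicate 1 or 2 or P10 replicate 1 (highest adjusted p = 0.0870 and 0.0674), and Nr4a3 without P0 replicate 1 or 2 or replicate 1 of P4, P6 or P10 (0.142). The count moved to 221 and 264 without P0 replicate 1 or 2, to 874 and 719 without P2 replicate 1 or 2, to 876 without P4 replicate 1, and to 795 without P6 replicate 1. It was 111 without P10 replicate 1, 4027 without P10 replicate 2, 908 with the replicate block, and 1413 without both P6 replicate 2 and P10 replicate 1, of which 713 were among the 1423.

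Of the 281 genes that rose and 280 that fell by passage 2, 191 and 246 were also called in the same direction at passage 10, and 4 in the opposite one. Independent lists of these sizes would share 24.6 and 23.1. Both comparisons use the same P0 libraries, so part of the excess may come from the shared controls. In 50 simulations with no change, 0 genes were shared, which says little since hardly any gene is called there. The simulations gave a gene the same spread in every passage, unlike the data. Across genes, the log2 changes correlated at 0.70, against 0.50 in the simulations, and their covariance was 0.355 against 0.0689, a difference of 0.286. With 1 P0 library for each comparison, a division chosen after the overlap was seen, 39 genes were higher and 29 lower in both (0.847 and 0.382 for independent lists) with P0 replicate 1 set against P2. With P0 replicate 2 set against P2 these were 42 and 12 (1.39 and 0.424). The correlations were 0.59 and 0.58 and the covariances 0.324 and 0.316. If the 2 P0 libraries came from 1 culture, this division does not remove what they share. Both comparisons also draw much of their spread from the same libraries, so the figures for independent lists are only a rough guide.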

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

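The 2 alternatives named last were chosen after the data were seen. The counts of called genes kept within 1.5-fold under both pseudocounts, no filter, a mean of at least 50, TMM rescaling and edgeR. With equal column totals, P2 gave 366 calls and the slope 782, and the median log2 change of all genes at P6 was 0.15 (-0.07 as deposited), 0.27 from P4 to P6 and -0.20 from P6 to P10, so that 66.8% of the P6 calls were higher against 49.9% as deposited. The replicate block gave 261, 767 and 908 calls for P2, P4 and the slope. The deviations of same-numbered libraries correlated above 0.1 in 1 of 10 pairs of passages (-0.67 to 0.23). This gives no sign that replicate numbers pair the samples, but a pairing cannot be excluded. The block also ended the list calls named in the report and 19 of 263 named gene results. With the libraries of the compared passages alone, P2, P4 and P10 against P0 gave 3940, 5677 and 49 calls, and P2 to P4 and P4 to P6 569 and 4. That fit takes the spread from fewer samples and leaves out that of the other passages. Its 49 calls at P10 are fewer than the 67 named genes that passed there in the main test, so not all of these passed in it. The duplicates differed by a median of 0.575 (absolute log2) at P10 and of 0.13 to 0.17 at P0, P2 and P4. The pooled spread of the main test is thus wide for the early passages and narrow for P10. The rank of the passage gave 2164 for the slope. DESeq2 gave 1061 at P2, 10, 463 and 67 for the later steps and 2716 for the slope. The cause was not tested for these. Camera gave 0 lists in each comparison with an estimated correlation, and 7 at P4 and at P6 on ranks. Leaving out 1 library gave 61 to 1578 calls at P2, 143 to 2783 at P4, 412 to 5441 at P6, 315 to 4738 at P10, 0 to 9, 0 to 3676 and 0 to 2936 for the 3 steps, and 111 to 4027 for the slope; lists ranged from 12 to 15, 10 to 11, 8 to 13 and 10 to 13. Without both P6 replicate 2 and P10 replicate 1 the counts were 4616, 5829, 6595 and 6256 against P0 and 220, 3712 and 3610 for the steps, and 6 list calls were lost (at P4 mesenchymal genes, adjusted p = 0.152, and leukocyte markers, 0.0911; at P6 and P10 integrins, 0.104 for each, and the amino acid response, 0.273 and 0.487). With the Dym covariate they were 3467, 4358 and 5840 at P2, P4 and P10, 41, 1 and 311 for the steps and 2672 for the slope. Over 5773 alternatives of 263 named gene results, 5132 kept direction and side, 468 lost the call, 173 gained it and 0 reversed; of 873 for called lists, 766 kept and 107 lost it. In simulated data with the same spread in every passage, unlike the data, 10% of 2-fold changes passed by limma and 27% by DESeq2 at P10 against P0.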

Other observations

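The contrasts of P10 against P2 and P4 and of P6 against P2, and all tests of explanations in this part were chosen after the results were seen, and the genes of this paragraph were taken for their shape over the passages. For Stab2 and Acoxl a first test, by correlation between genes, was judged void because the genes had been picked for moving together. It was replaced by ratios after its value was seen, at first over 7 libraries and then over all 10, and the explanation tested for the immediate early genes was narrowed after its value was seen. A first test of it, on 9259 genes (68.5% of those tested), was replaced, since the normalisation centres so wide a set near 0. Several genes were high at P2 or P4 and lower again at P10. Agt fell between P4 and P10 (log2 change -3.94, SE 0.35, limma adjusted p = 0.00431), from 1450 ± 3.26 to 97.1 ± 38.2 normalised reads. Fabp4, a fatty acid carrier, went from 19.6 ± 0.68 at P0 to 996 ± 28.8 at P4 and 136 ± 7.49 at P10 (P10 against P4 -2.87, SE 0.22, adjusted p = 0.00210). Lum fell from 211 ± 22.2 at P2 to 6.20 ± 4.36 at P10 (-5.02, SE 0.55, adjusted p = 0.00598), Postn from 683 ± 80.3 to 86.5 ± 19.7 (-2.98, SE 0.22, adjusted p = 0.000989) and Col6a1 by 2.33 (SE 0.26, adjusted p = 0.00641). Angpt4, an angiopoietin, and Il1r2, a decoy receptor of interleukin 1, were lower at P10 than at P4 by -3.01 and -2.95 (SE 0.20 and 0.21, adjusted p = 0.00168 for each). In all, 84 genes rose and 86 fell between P2 and P10, 7 rose and 23 fell between P4 and P10, and 29 rose and 22 fell between P2 and P6.

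Lists that were called in none of the 4 comparisons with P0 were fatty acid synthesis, cell-cell adhesion, the unfolded protein response, glycolysis, hypoxia targets, p53 targets, metal handling, growth factor receptors and ligands, neural and muscle markers, and glycosylation and secretion. Their lowest camera adjusted p was 0.103, for glycolysis at P2, where 1 of 23 genes fell. At P10, 1 glycolysis gene rose and 1 fell, fatty acid synthesis had 2 of 13 genes higher and none lower, and cell-cell adhesion 2 of 24 lower and none higher. Of the unfolded protein response 2 of 29 rose and 5 fell, of hypoxia targets 2 of 19 rose and 2 fell, of p53 targets 3 of 24 rose and 4 fell, of metal handling 2 of 16 rose and 3 fell, of growth factor receptors and ligands 4 of 23 rose and 4 fell, and of glycosylation and secretion 3 of 33 rose and none fell. None of 5 neural and muscle genes passed. The median and mean log2 change at P10 differed in sign for fatty acid synthesis (-0.12 and 0.00), the unfolded protein response (0.09 and -0.07), hypoxia targets (-0.22 and 0.02), growth factor receptors and ligands (-0.22 and 0.13) and neural and muscle genes (0.15 and -0.03). Of 14 leukocyte markers matched, 5 reached the tested level, with Cd68 the most abundant at 66.2 normalised reads on average. Of 14 epithelial markers matched, Cdh1 was the most abundant at 186, and of 13 endothelial markers Flt1 at 66.0.

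Ribosomal RNA features stood out in P2 replicate 2, with 239094 normalised reads at Rna28s1 against 11001 in P2 replicate 1 and 571 to 13514 in the other 8 libraries.

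The duplicates of P10 differed by a median of 0.57 (absolute log2) and those of P6 by 0.43, against 0.13 to 0.17 at P0, P2 and P4. Without the 50 most abundant features and with equal totals, the P10 median was 0.574. This does not decide whether a few abundant features played a part. A median over all tested genes, of values already scaled by DESeq, hardly moves when 50 features are removed. P10 replicate 2 correlated most with P4 replicate 1 (0.979), and less with its own duplicate (0.930). No library of P6 or P10 was closest to its own duplicate. P6 replicates 1 and 2 correlated most with P10 replicate 1 (0.973 and 0.977), and P10 replicate 1 with P6 replicate 2 (0.977). The P6 duplicates correlated at 0.956. The median of the DNA replication list in P10 replicate 2 lay 0.84 above the P4 mean (quartiles 0.70 and 0.94). Over P0, the list medians were 0.15 to 0.30 in the P2 and P4 libraries and 1.05 in P10 replicate 2. Igfbp4 and Aqp1, named from prior knowledge, had 344 and 44.5 normalised reads in P10 replicate 2. In the P2 and P4 libraries they had 667 to 1084 and 273 to 536. These values argue against a library of P2 or P4 carrying its label. The list is the weaker part, since it was called at P10 with that library included. Differences in RNA quality or library preparation, and real differences between cultures, cannot be told apart here. The difference of P10 replicate 1 from 2 and that of P6 replicate 2 from 1 correlated at 0.67 across genes, which both could give and which is the lowest value of the pairing check with its sign turned, not a separate measurement.

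Stab2, Acoxl and Dtnb, which lie on 3 different chromosomes in the reference, had values near those of P0 in P6 replicate 1 (mean log2 difference -0.39) and far above it in P6 replicate 2 (5.17) and at P2, P4 and P10 (mean 5.76). Whether reads of 1 source were counted at both Stab2 and Acoxl stays open: their ratio moved by 1.74-fold over the 10 libraries and by 1.16-fold over the 7 with more than 1000 of each, and a steady ratio would decide nothing, since the pair was picked for moving together. The ratio of Dtnb to Stab2 moved by 5.31-fold over the 10 libraries, with its highest value in P6 replicate 1, where both features were near P0. Over the 7 libraries it moved by 4.09-fold. It was 2.32 in P6 replicate 2 and 2.74 in P10 replicate 1, and 0.67 to 0.93 at P2, P4 and in P10 replicate 2. This argues against 1 source counted at both features in a fixed proportion, but rests on those 2 libraries with high ratios. An effect of passage stays open, since only 1 library departs from it and the labels name no reason for it.

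Of 20 immediate early genes, 4 fell and 2 rose at P2, and 10 fell and 1 rose at P10 (adjusted p = 0.485 and 0.441 with an estimated correlation). The 4 that fell at P2 were Egr2, Fos, Fosb and Nr4a1, by 1.66 to 4.38 log2. For each of them, the other tested genes within 2-fold of its P0 mean had a lower quartile of -0.34 to -0.26. These were 24.4 to 31.6% of the tested genes, and most of them did not share the fall. Whether a general change of transcripts at their levels played a part is not decided by this. The 4 were picked for having fallen, and the normalisation holds the bulk of genes near 0. Time since feeding, handling at harvest and an effect of the medium stay open and were not tested, because the labels give no times.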
